A study of Rattus norvegicus with 14 samples.

How the data were processed

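RRBS libraries were prepared from 100 ng of genomic DNA of the left soleus with a Diagenode RRBS kit after MspI digestion, and bisulfite conversion and PCR were done on pools of libraries, per the labels' protocols; which libraries shared a pool is not given in the sources used here. Per the submitters' processing notes, reads were checked with FastQC, trimmed with Trim Galore 0.6.10 and aligned with Bismark and Bowtie2 to rn7; the versions of the last ones are not given in the sources used here. The deposited table gives the percent methylation of each library in non-overlapping windows of 1000 bp. Per the file headers, a window has one value per library, a chromosome, a start and an end, and no read count. The coverage minimum, the tool that formed the windows, the treatment of duplicate reads and the rule for missing values are not given in the sources used here. In the file, each of the 194367 windows has a value in at least 4 HCR and 4 LCR libraries, which was tested on the values. Because a window averages all its covered cytosines, a change at one CpG is diluted by its neighbours, and a library that covers other CpGs of a window can differ in level without a difference in methylation. Depth is unknown, so no counting interval was computed and all errors are spreads between libraries.

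Columns were matched to samples by the library names in the labels, and groups were taken from the sample titles; 0 sample columns were left unused. The choices of test, threshold, alternatives and the rule for naming windows were made before the data were examined, except where stated. The planned tests for single CpGs, promoters, gene lists and genomic features were not run, since they need counts or values per CpG, or gene positions on rn7; the gene table at hand is of another assembly, GRCr8, and its coordinates were not used. Windows are therefore given by position only.

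For the windows, levels were divided by 100 and transformed to log2((level + 0.01)/(1 - level + 0.01)), a log2 logit, and compared with limma 3.58.1 in R 4.3.3, with line as the only factor, a variance trend in the empirical Bayes step, all 14 samples and 2-sided p-values adjusted by Benjamini-Hochberg over 135802 windows. A window was called at an adjusted p under 0.05. The offset keeps windows at 0 finite and shrinks their log2 logit differences; differences in percentage points are untransformed. The windows named in the text are the 5 called windows with the largest higher and the 5 with the largest lower level in HCR. The procedure was tested on simulated data with the means and moderated spreads of the 135802 real windows. Of 100 windows changed by 1 log2 logit unit 45 were called, and of 100 changed by 2 units 93 were called. Of the unchanged windows 4 were called. All changed windows were of middle level, and the noise was normal and independent between windows. Recovery at low or high levels, or with noise shared between windows, was therefore not tested.

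Mean levels were compared with exact permutation tests over all 3003 splits of 14 samples into 6 and 8. Levels were also compared in 5 classes of the mean over all samples (under 10, 10 to 30, 30 to 50, 50 to 70 and at least 70%) and per chromosome. Distances between samples are mean absolute differences over the common windows. Pairs of called windows were counted by distance and set against 1000 draws of tested windows matched on level and within-line spread, and against 1000 matched on chromosome and level. The classes, distances, pairs and clusters were chosen after seeing the data. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

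Alternatives were autosomes only, no moderation of the variance, untransformed levels, an offset of 0.05, minimum differences of 10 and 25 points, a replicate block and leaving out each sample. Added after seeing the data were centring of each library, quantile normalization, the number of windows without a value as a covariate and library weights. So were the 12 samples of the block fitted without it, only windows with mean levels of 5 to 95%, and all 194367 windows. Leaving out windows with one sample at 15% or less and one at 75% or more was also added then. Replicate numbers 1 to 6 occur in both lines, and nothing in the labels ties a number to a shared litter or day.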

Results

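DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) in the left soleus, a postural muscle rich in slow-twitch fibres, of female rats aged 23 to 24 months. RRBS cuts genomic DNA with MspI at CCGG sites, selects short fragments and converts unmethylated cytosines with bisulfite, so that mainly CpG-rich sequence is read. The rats came from generation 44 of 2 lines selected from a common outbred stock for high (HCR) or low (LCR) running capacity. There were 6 HCR and 8 LCR samples, all taken at baseline, and the question was which methylation differences accompany inherited aerobic capacity in old muscle. The samples are numbered as replicates, and nothing in their labels states that each came from a different rat, so p-values measure the spread between these samples only.

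Methylation levels were given for 194367 windows of 1 kb on rn7. Each window had values in at least 4 HCR and 4 LCR samples, and 135802 windows (69.9%) had a value in all 14 samples. These common windows were used throughout unless stated. Read depth was unknown, because the values were percentages without counts. The number of windows with a value ranged from 170846 in LCR replicate 7 to 191662 in LCR replicate 4. HCR samples lacked a value in 10130 ± 4427 windows (SD, n = 6) and LCR samples in 9908 ± 7162 (SD, n = 8), and this difference was smaller than the spread between samples (exact permutation test, two-sided, p = 0.946). Windows under 10% methylation made up 26.6% of the common windows, and windows at 70% or more made up 10.8%.

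Mean methylation was higher in the HCR samples, but by an amount that did not pass the exact test at 0.05. It averaged 36.0% ± 0.98 in HCR (SD, n = 6) and 34.8% ± 1.04 in LCR (SD, n = 8), a difference of 1.12 percentage points (SE 0.543; exact permutation test over 3003 splits, two-sided, p = 0.0683). The interval of differences that the exact test does not reject at 0.05 ran from -0.0819 to 2.28 points. On the X chromosome, of which females carry one active and one inactive copy, the levels were 47.5% ± 0.925 in HCR (SD, n = 6) and 46.7% ± 1.07 in LCR (SD, n = 8), a difference of 0.768 points (exact p = 0.183), which is -0.35 points relative to the genome-wide difference. On the mitochondrial genome, whose level mostly reflects cytosines that escaped conversion, HCR samples averaged 0.610% ± 0.169 (SD, n = 6) and LCR samples 0.631% ± 0.346 (SD, n = 8; exact p = 0.918). In the deposited levels all 20 autosomes and X had a higher mean in HCR, by 0.768 to 1.31 points. The chromosomes were read in the same libraries, so their shared direction is not independent of the genome-wide difference. After Benjamini-Hochberg adjustment over these 21 chromosomes 0 passed 0.05 in the exact test, and 4 had an unadjusted p under 0.05. Leaving out HCR replicate 3 raised the difference to 1.47 points (exact p = 0.0163), and leaving out LCR replicate 1 raised it to 1.36 points (exact p = 0.0256).

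The line difference in level passed the test at both ends of the methylation range. In the 36138 windows with a mean under 10%, HCR samples averaged 3.32% ± 0.189 (SD, n = 6) and LCR samples 2.96% ± 0.156 (SD, n = 8; exact permutation p = 0.004, adjusted p = 0.00999 over 5 classes). In the 14706 windows at 70% or more, HCR samples averaged 76.7% ± 0.257 and LCR samples 76.0% ± 0.303, a difference of 0.698 points (exact p = 0.00167, adjusted p = 0.00833). Differences were larger in the middle classes, at 1.74 points for windows of 10 to 30%, 1.75 points for 30 to 50% and 1.15 points for 50 to 70%. The spread between samples was larger as well, and the adjusted exact p-values were 0.105, 0.123 and 0.105. With the number of windows without a value as covariate these classes passed (adjusted permutation p = 0.0213, 0.0213 and 0.0189). They also passed without HCR replicate 3 or without LCR replicate 1 (adjusted exact p up to 0.0495), and in no other setting run. Relative to the genome-wide difference of 1.12 points these 2 outer classes stood at -0.758 and -0.42 points, which follows from subtracting one value from every class and is no test of their direction.

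Mean methylation fell as the number of windows without a value rose. Across all 14 samples Pearson's r was -0.70 (permutation p = 0.00481, adjusted p = 0.0144 over 3 relations) and Spearman's rho -0.63 (permutation p = 0.0181, adjusted p = 0.0333). Within HCR (n = 6) r was -0.90 (exact permutation p = 0.0167, adjusted p = 0.0167) and rho -0.89 (exact p = 0.0333, adjusted p = 0.0333). Within LCR (n = 8) r was -0.82 (exact permutation p = 0.0114, adjusted p = 0.0167) and rho -0.79 (exact p = 0.0279, adjusted p = 0.0333). Without the 2 samples farthest from the median number, r was -0.46 over all samples, -0.80 in HCR and -0.73 in LCR. With that number as a covariate the line difference was 1.15 points (SE 0.324; permutation of the line labels over all 3003 splits, p = 0.0127).

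**Figure D1:**
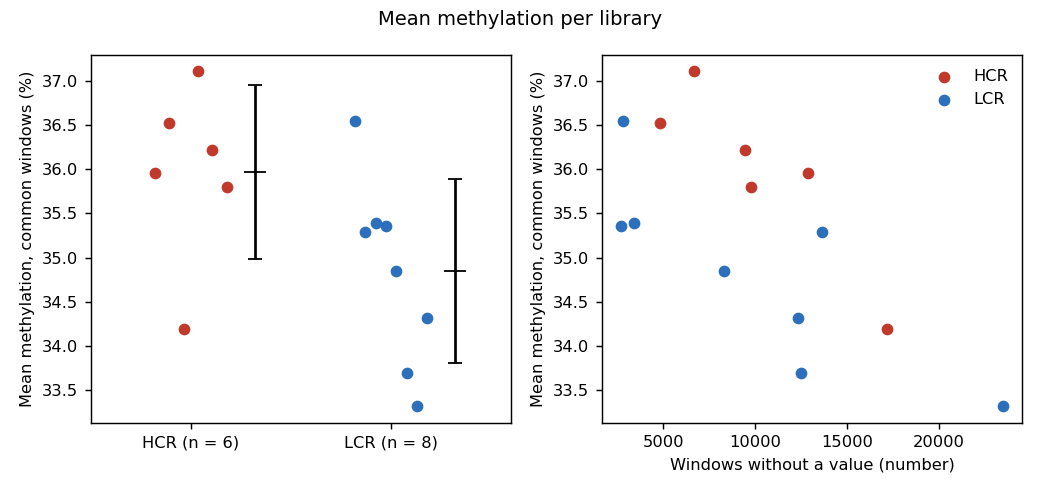
Mean methylation over the common windows (%, y axis) for each library, by line on the left and against the number of windows without a value (x axis) on the right. Points are libraries, and the dash and bars on the left are the mean and SD of each line; the axes do not start at 0. HCR averaged 36.0% and LCR 34.8% with overlapping values, and in both lines libraries that lacked more windows had lower means.

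The lines differed at 773 of 135802 windows (0.569%) by limma with Benjamini-Hochberg adjusted p under 0.05, of which 550 were higher and 223 lower in HCR. The median size of the difference was 15.98 percentage points, with quartiles of 11.6 and 21.7. A difference of at least 10 points was seen in 633 windows, 444 higher and 189 lower in HCR, and one of at least 25 points in 129, 84 higher and 45 lower. In 547 of the 773 windows the HCR and LCR samples did not overlap at all; over all windows tested 0.71% were separated in this way, against 0.0666% expected by chance for 6 against 8. The excess of windows higher in HCR depended on scale: with each library centred on its mean the calls were 342 higher and 326 lower, and after quantile normalization 357 higher and 318 lower. Leaving out HCR replicate 2 reduced the calls to 495, with 332 higher in HCR, and the number higher in HCR fell to 345 without HCR replicate 4 and to 361 without HCR replicate 6.

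The 5 windows with the largest higher level in HCR lay on chromosomes 4, 10, 1, 16 and 17, and their levels were 42.3 to 50.2 points above those of LCR. The window at 69809001 to 69810000 on chromosome 4 was methylated at 76.0% ± 9.43 in HCR (SD, n = 6) and 25.8% ± 10.6 in LCR (SD, n = 8), with a log2 logit difference of 3.33 (SE 0.42, limma adjusted p = 0.00138). On chromosome 10, the window at 60695001 to 60696000 had 61.1% ± 15.4 in HCR and 11.03% ± 7.92 in LCR (limma adjusted p = 0.017), and its adjusted p was 0.0549 without moderation of the variance. The window at 260517001 to 260518000, the last one measured on chromosome 1, had 66.9% ± 3.00 in HCR and 21.9% ± 9.26 in LCR (limma adjusted p = 0.000376). At 27213001 to 27214000 on chromosome 16 the levels were 73.4% ± 8.15 and 28.7% ± 8.55 (limma adjusted p = 0.000294). At 6833001 to 6834000 on chromosome 17 they were 54.1% ± 14.3 and 11.8% ± 11.2 (limma adjusted p = 0.0215). The chromosome 17 window no longer passed 0.05 without HCR replicate 2 (limma adjusted p = 0.0603), without HCR replicate 5 (0.0539) or without moderation of the variance (0.0617). Over all alternatives its adjusted p ranged from 0.00548 to 0.0783, and that of the chromosome 10 window from 0.000906 to 0.16.

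The 5 windows with the largest lower level in HCR lay on chromosomes 2, 10 and 5. At 92294001 to 92295000 on chromosome 2 HCR samples had 22.7% ± 11.3 (SD, n = 6) and LCR samples 76.1% ± 6.26 (SD, n = 8), a log2 logit difference of -3.55 (SE 0.37, limma adjusted p = 0.000293). A second window on this chromosome, at 1364001 to 1365000, had 13.5% ± 4.14 and 55.5% ± 11.5 (limma adjusted p = 0.000288). At 163248001 to 163249000 on chromosome 5 HCR samples were nearly unmethylated at 1.81% ± 2.34, against 43.1% ± 11.9 in LCR (limma adjusted p = 0.000123). The other two lay on chromosome 10, at 79833001 to 79834000 with 25.1% ± 8.56 and 70.4% ± 3.89 (limma adjusted p = 6.95e-05), and at 80127001 to 80128000 with 27.5% ± 23.5 and 70.01% ± 6.45 (limma adjusted p = 0.0222). In this last window HCR replicate 4 stood at 74.6% and the other HCR samples between 11.9% and 24.2%. Its call was lost without HCR replicate 1, 2, 3 or 6 (limma adjusted p = 0.053, 0.0582, 0.0512 and 0.0585) and without moderation of the variance (0.0651), and over all alternatives its adjusted p ranged from 3.27e-05 to 0.172. Near-complete absence of methylation in one line, with a mean under 5% against at least 20% in the other, was found in 10 called windows for HCR and in 10 for LCR. The genes at these positions were not analysed here.

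**Figure D2:**
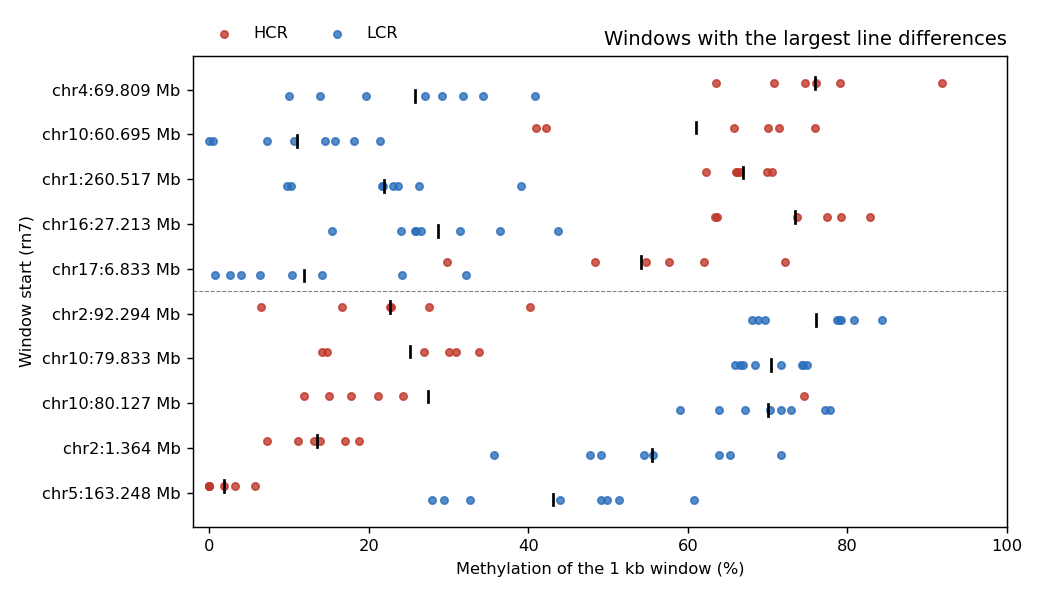
Methylation (%, x axis) of the 5 windows with the largest higher and the 5 with the largest lower level in HCR, named on the y axis by chromosome and start on rn7. Points are samples, 6 HCR and 8 LCR, and black ticks are line means. In the window starting at 80127001 on chromosome 10, HCR replicate 4 lies at 74.6%, among the LCR samples.

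Called windows were spread over all 20 autosomes and X, with unequal density. Chromosome 7 held 76 called windows (0.947% of those tested there) against 0.545% elsewhere, an odds ratio of 1.74 (Fisher's exact test, adjusted p = 0.000348 over 21 chromosomes). Of these 60 were higher and 16 lower in HCR, and the calls after centring each library were 40 higher and 23 lower. Chromosome 2 also held 76 (0.884% against 0.548% elsewhere, odds ratio 1.62, Fisher's exact adjusted p = 0.00204), 45 higher and 31 lower in HCR; the calls made there after centring each library, a set of 74, were 30 higher and 44 lower. Chromosome 17 was denser (odds ratio 1.57, Fisher's exact adjusted p = 0.0375) and chromosomes 3 and 15 sparser (odds ratios 0.634 and 0.409, Fisher's exact adjusted p = 0.0322 and 0.0161), but these 3 lost their calls in 9, 10 and 7 of the 14 fits that each left out a sample. The calls of chromosomes 7 and 2 were kept in those 14 fits. With only the 12 samples numbered 1 to 6 both were lost (odds ratios 1.62 and 1.59, Fisher's exact adjusted p = 0.063 for each). That of chromosome 2 was also lost among the fewer windows differing by at least 25 points, though its odds ratio there was 1.95 (Fisher's exact adjusted p = 0.209). The X chromosome held 17 called windows (0.452%, odds ratio 0.789, Fisher's exact adjusted p = 0.496). Neighbouring windows are not independent, so these p-values are too small. The 15 tested windows on the Y chromosome and the 10 on the mitochondrial genome gave 0 calls by limma, with 1 and 0 at an unadjusted p under 0.05.

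Called windows lay close together. There were 716 pairs of called windows within 1 Mb of each other, against a mean of 373 and a highest value of 467 in 1000 random draws of tested windows matched on level and spread. The excess was present at each distance, with 13 adjacent pairs against 0.83 expected, 11 against 4.59 at 2 to 10 kb, 94 against 38.5 at over 10 to 100 kb and 598 against 329 at over 100 kb to 1 Mb; at 2 to 10 kb the highest draw was 12. Both windows changed in one direction in 12 of the 13 adjacent pairs, in 5 of the 11 pairs at 2 to 10 kb (45.5%) and in 64.5% of pairs at over 10 kb to 1 Mb, against 58.9% of pairs on different chromosomes. Joining called windows at most 500 kb apart gave 62 clusters of 3 or more, which held 257 windows (33.2% of the calls). Windows of both directions were found in 38 of these clusters. How many mixed clusters random directions would give was not computed, so this count is no trait of the clusters.

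The largest cluster, chosen after the data were seen, spanned 2090001 to 4905000 on chromosome 2. It held 15 called among 92 tested windows, 8 higher and 7 lower in HCR (6 and 8 among the calls made after centring or quantile normalization), with differences from -37.8 to 23.8 points. The next, at 103145001 to 103972000 on chromosome 10, held 10 of 202, 6 higher and 4 lower (3 and 5 among the calls made after centring or quantile normalization), from -37.5 to 26.6 points. On chromosome 17 the interval from 8410001 to 10233000 held 8 of 333, 7 of them higher in HCR. Among the calls made after centring or quantile normalization 5 were higher and 1 lower there. The 5 clusters of 7 windows differed in direction. All 7 were higher in HCR on chromosome 7 at 127781001 to 128873000, by 10.6 to 28.8 points. On chromosome 19 at 23383001 to 24131000 and on chromosome 10 at 83403001 to 84351000, 6 of 7 were higher. Among the calls made after centring these clusters held, in this order, 5, 5 and 4 higher and 0, 1 and 1 lower. After quantile normalization they held 6, 4 and 3 higher and 0, 1 and 1 lower. The other two were mixed, with 3 higher and 4 lower on chromosome 10 at 12443001 to 13110000, and 4 higher and 3 lower on chromosome 13 at 39016001 to 40122000 (3 and 3 among the calls made after centring or quantile normalization).

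**Figure D3:**
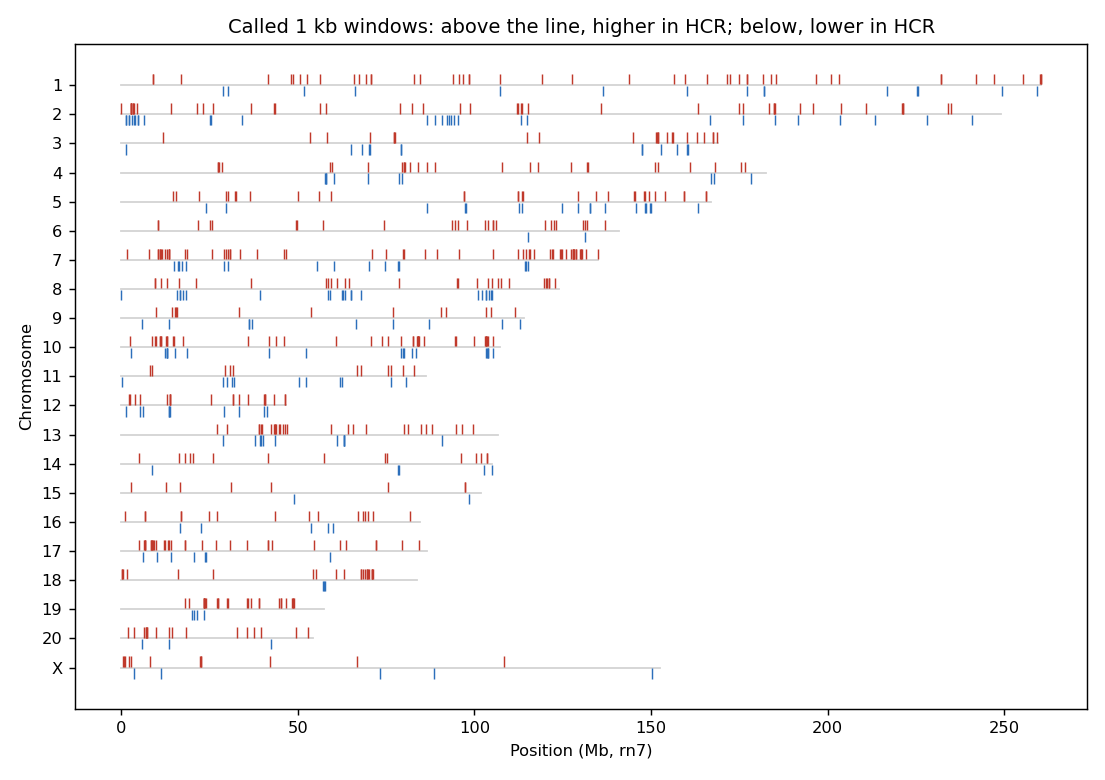
Positions of the called windows on the autosomes and X (x axis, Mb on rn7; y axis, chromosome). Each tick is one window with limma adjusted p under 0.05; ticks above a line (red) are higher and ticks below (blue) lower in HCR, 550 and 223 in all with those on unplaced scaffolds, which are not drawn. Ticks gather in clusters on several chromosomes.

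**Figure D4:**
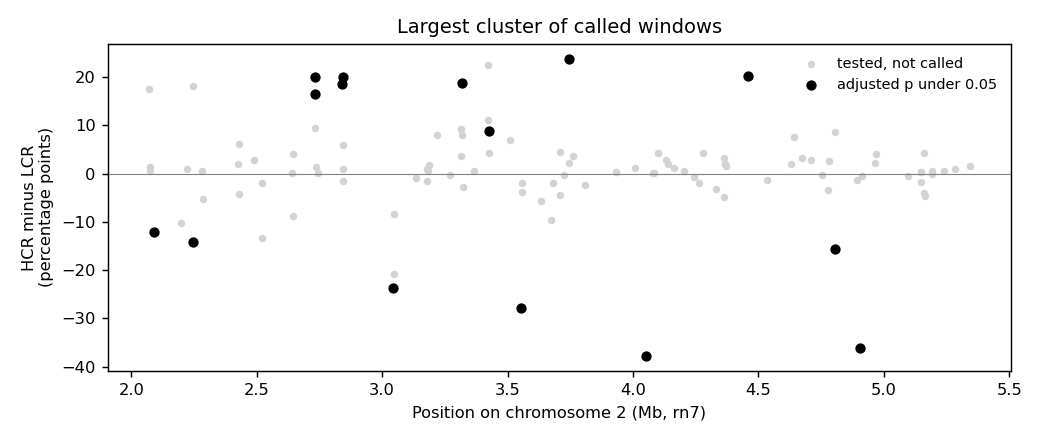
Difference in methylation between the lines (HCR minus LCR, percentage points, y axis) for the tested windows in and 500 kb around the largest cluster on chromosome 2 (x axis, Mb on rn7). Black points are the 15 called windows, 8 above and 7 below 0 in the deposited levels (6 and 8 among the calls made after centring), and grey points are windows that did not pass the test.

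Samples of different lines were on average farther apart than samples of one line, but the nearest sample did not tell the lines apart. The mean absolute difference between 2 samples over the common windows was 6.03 percentage points between lines, 5.92 within HCR and 5.53 within LCR. The difference of the between-line mean from the mean within lines was 0.363 points, and this was the largest value of all 3003 splits (exact permutation test, one-sided, p = 0.000333, the smallest it can give). The mean within lines pools both lines and holds more LCR than HCR pairs, so the closer LCR samples lower it. This difference can therefore also respond to unequal spread within the lines. For all 8 LCR samples the nearest sample was another LCR sample, whereas for 0 of the 6 HCR samples it was an HCR sample. HCR replicate 4 was nearest to LCR replicate 1 and the other HCR samples to LCR replicate 4. LCR replicate 4 was also the nearest sample of most other LCR samples. LCR replicates 4 and 1 lacked a value in the fewest windows of all samples, 2705 and 2823. Whether nearness followed this number rather than likeness of the lines was not tested. HCR samples were 0.389 points farther from each other than LCR samples were, which did not pass the test (exact permutation test, two-sided, p = 0.337). The closest 2 samples differed by 4.66 points, so no pair of libraries held identical values.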

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

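The tests of outlying samples were fixed beforehand, and the remark on chromosome Y was chosen after the values were seen. Of 30 sets of values tested for an outlying sample (5 library measures and 10 named windows, each per line), 1 held one, where chance gives about 1 in 20. In the window at 80127001 to 80128000 on chromosome 10, HCR replicate 4 had 74.6% methylation and the other HCR samples 11.9% to 24.2%. Its distance to the next sample was 0.803 of the range. The LCR samples of that window averaged 70.01% ± 6.45 (SD, n = 8), and without HCR replicate 4 the line difference was -52.0 points. In the named window at 79833001 to 79834000 on the same chromosome HCR replicate 4 had 30.03%, and the HCR samples averaged 25.1% ± 8.56 (SD, n = 6).

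Although all samples came from females, 32 windows were assigned to chromosome Y. In the 15 of them with a value in every sample, the mean level was 59.6%, and the samples ranged from 56.4% to 62.6%. HCR samples averaged 59.8% ± 1.56 (SD, n = 6) and LCR samples 59.4% ± 1.93 (SD, n = 8; exact permutation p = 0.713).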

How the results depend on the processing

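Centring, quantile normalization, the covariate, the weights, the filters on windows, the medians and the means over own windows were chosen after seeing the data. So were the 12 samples of the block fitted without it, and every setting for level classes, distances, close pairs and chromosomes. The count of 773 called windows was within 1.5 times its value under 12 of 15 other settings, autosomes, untransformed levels and an offset of 0.05 included. It was 129 with a minimum difference of 25 points, where 84 were higher and 45 lower in HCR. Leaving out each sample gave 495 to 669 calls, 332 to 503 of them higher in HCR. Of these calls 452 to 590 were shared with the 773, and these fits have fewer samples. Without moderation of the variance 635 windows were called, and 530 of them were shared. The number higher in HCR was 342 after centring and 357 after quantile normalization, since both remove the difference in library means, and 564 and 575 of the calls were then shared with the 773. With the replicate block on the 12 samples whose numbers occur in both lines, 71 windows were called, 42 higher and 29 lower in HCR; without it the same 12 samples gave 444, 291 higher in HCR; with 12 samples the test has fewer values. Same-numbered samples did not deviate together over all windows. The correlations of their deviations ran from -0.0317 to 0.0336, and 0 of 6 HCR samples correlated best with their own number. These values show no strong shared deviation, but they cannot tell whether same-numbered samples shared a litter, day or pool. Under the block the calls of chromosomes 7 and 2 had odds ratios of 1.47 and 2.15 (Fisher's exact adjusted p = 0.733 and 0.466), and the global difference was 0.777 points (exact p = 0.219). The global difference of 1.12 points kept its direction in all settings run, passed 0.05 with the number of windows without a value as covariate (1.15 points, permutation p = 0.0127), and ranged from 0.89 to 1.47 points when each sample was left out; the cause of these passes was not tested. As a difference of medians over windows it was 1.88 points (exact p = 0.157), and over each library's own windows 1.14 points (exact p = 0.193). The distance between lines and the excess of close pairs passed their tests in every setting run for them, but the 2 outer level classes did not under the block: their differences were then 0.315 and 0.616 points, with the smallest p that 6 pairs can give (exact p = 0.0312, adjusted p = 0.0781 over the classes for each). Without each sample in turn they were 0.312 to 0.428 and 0.634 to 0.782 points, with adjusted exact p up to 0.0214. The 10 named windows kept direction in 285 of 285 fits and lost the call in 16, of which 6 were under the block. They were chosen as the largest differences in these same data, and several fits share the main coefficient. Their kept direction is therefore no independent support. Alternatives on coverage, 500 bp windows and CpGs per window, and all those for single CpGs, promoters, gene lists and genomic features, were not run, since the values are levels of 1 kb windows. Depth is unknown, and the simulated recovery of 45 of 100 middle-level windows changed by 1 log2 logit unit limits what the absence of a call shows.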

Other observations

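The comparisons between chromosomes and of ranges, the tests of random splits, of conversion and of the windows without a value were chosen only after the result was seen, while the bounds of the other tests were set before their values were computed. The X chromosome differed from the autosomes in its methylation profile in these females. Only 6.07% of its 3758 common windows had a mean under 10%, against 27.2% of 131799 autosomal windows, and 52.1% were at 50% or more, against 34.5%. Its mean level over the 14 samples was 47.1% ± 1.05 (SD), against 35.0% ± 1.14 on the autosomes. The 220 windows on unplaced scaffolds averaged 51.5%, and 10 mitochondrial windows averaged 0.622%, with samples from 0.121% to 1.19%.

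A few called windows were uniform in one line and variable in the other. In 5 of the 773 the HCR samples spanned at least 40 points while the LCR samples stayed within 15, and in 9 the reverse held. Windows near 0 in one line and at 20% or more in the other numbered 10 for each line. Those near 0 in HCR came from the 223 windows called lower in HCR, and those near 0 in LCR from the 550 called higher.

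Random regrouping of the samples did not reach the count of 773 called windows. Among 100 splits of the 14 samples, drawn from 3003 and including the real one, 1 split, the real one, gave as many. The highest of the others called 2 windows, and 86 of the other 99 called 0. The splits treat the samples as exchangeable and concern the count only, so single windows among the 773 can still be false calls.

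The higher mean level of the HCR libraries was weighed against technical explanations. Incomplete conversion would need 1.73 points more unconverted cytosine in HCR, but the mitochondrial windows differed by -0.0205 points (SE 0.141). The number of windows without a value tracked the level within both lines, but it was similar in them, at 10130 in HCR and 9908 in LCR. As a covariate it could therefore change the difference little, and the adjusted value was 1.15 points. This says nothing about read depth, which is unknown. Without the called windows 97.3% of the difference was left, which is no test of them as its source, since so few windows can carry at most 27.2% of it. Also open is a difference in other properties of the libraries, read depth and pools converted together included. A difference in the cell types of the muscle, or between the lines themselves, stays open as well. None of these was tested.

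Called windows lay close together, and uneven placing of the tested windows is argued against by 716 pairs within 1 Mb, where the highest matched draw had 467. A candidate explanation is that the lines, bred apart up to generation 44, became fixed for different stretches of chromosome whose sequence differences act on methylation nearby or change CpGs themselves. Fixed differences do not vary within a line and were not tested; for variants that still segregate within a line, strong negative correlations (r under -0.7) were more frequent at 10 kb to 1 Mb than between chromosomes on 14 of 20 autosomes in HCR and 13 in LCR, which decides nothing about fixed ones. For both lines together, a measure not set in advance, the count was 15. A broad change in one direction cannot be told apart either. Pairs 10 kb to 1 Mb apart shared direction 5.58 points more often than pairs on different chromosomes. This lies between the bounds of 5 and 20 set in advance. With each autosome left out in turn, these near pairs shared direction in 61.7% to 67.0%, against 58.9% of all pairs on different chromosomes. The shares were computed on the deposited levels, where most calls were higher in HCR. Selection and drift between the lines both remain open.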
